A study of Mus musculus with 4 samples.

How the data were processed

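RNA from the lymph nodes of 4 EAE mice, 2 given BrQ and 2 given vehicle, was extracted with TRI Reagent, and RNA with an integrity number above 8 was sequenced in paired ends, per the labels' protocols. Per the submitters' processing notes, Trim Galore 0.6.2, HISAT2 2.1.0 and HTSeq 0.11.2 were used with the mm10 genome. The annotation release and the strand setting of the counting are not given in the sources used here. The deposited values are raw read counts per gene, 1 table per mouse, with 56748 gene IDs each and 5 closing rows that name no gene. Those rows, mostly reads in no feature, were kept out of library sizes and tests; they took 86.8% to 88.8% of all read rows. Groups and replicate numbers came from the sample titles. Chi-square per degree of freedom between libraries was 13.9 within BrQ and 31.1 within Vehicle, so no library was a copy of another.

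Gene positions came from GENCODE M21 on GRCm38, which held 52073 of the IDs. The other 4675 included all 2147 IDs of a later numbering series (starting ENSMUSG00002). To find where names and reads meet, a chain with 2 states ran along chromosomes 1 to 19 and X. It used the mean count over the 4 libraries, without using treatment. A panel gene (families picked by symbol, most of them used in most cell types) scored if it had 100 reads, most other protein-coding genes if they had 50. Ribosomal protein genes and predicted gene models (Gm and Rik symbols) were left out of the chain. So were the olfactory, vomeronasal and taste receptor, Mup, defensin and keratin families, so a segment can extend across them. The settings of this chain were changed repeatedly after its output had been looked at. An exploratory chain, which used olfactory and vomeronasal receptor genes as an unexpressed panel, was dropped because it called receptor clusters. Then 5 settings followed. Setting 1 gave 6 segments, some of them short and gene-dense, with a ribosomal protein gene near 0 reads inside. Setting 2 relaxed the scores and required 2 Mb, giving 3 segments on chromosomes 4 and 15. Setting 3 removed tissue-restricted families from the panel, partly after their low counts were seen, and gave the same 3. Setting 4 was loosened because the starts of chromosomes 6 and 18 looked right and were missed, and gave 9. Setting 5 required 80% of the panel genes in a segment to have 100 reads, which left 5, and is the one reported. No test between groups had been run by then, but the counts per library of several abundant genes, among them Samd9l on chromosome 6, had been seen, and so had those of Rps20 and Rpl30. Counts under each setting are given with the results. Displaced intervals were not reassigned to other genes, since that would convert coordinates between builds.

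Differential tests used edgeR 4.0.16 (quasi-likelihood, default dispersion, filterByExpr, TMM) in R 4.3.3 on all 4 libraries with group as the only term, with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values are TMM scaled. Gene lists were tested with camera in limma 3.58.1 (log2 CPM with a prior count of 2, preset correlation 0.01) when at least 3 members were tested: 35 of 38 lists. Groups, lists, tests, the rule for named genes and most alternatives were fixed before the data were examined. That rule takes the 10 largest changes per direction among features past the threshold, with a mean of at least 1 CPM, both BrQ libraries on one side of both Vehicle libraries and a protein-coding style symbol; 11 fixed genes; and up to 4 members of each list described. Some genes that this rule names are not reported here. Alternatives were other scaling factors, other low count filters, the legacy quasi-likelihood fit, the replicate number as a block, each library left out, DESeq2 1.42.0 and limma voom. Figures were drawn with matplotlib 3.10.9.

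On simulated counts for BrQ vs Vehicle, with the means and library sizes of these data, 200 features were changed and 9892 were tested. The edgeR test recovered 32 of 100 changed 2-fold and 77 of 100 changed 4-fold, with 5 false calls among 114. The simulated changes went up or down at random, and most features were left unchanged. In the real libraries 4676 of 10223 passed and the direction split moved with the scaling, so 5 of 114 is no estimate of false calls there. A scan for shifted labels was tested on simulated counts of chromosome 11 moved by 80 kb: 7 of 8 windows past their permutations gave the shift within 5 kb. Simulated without a shift, 0 of 12 windows passed. The score of the scan is centred, which sets it at or near 0 for a shift of 0. Names in place could therefore not be found, so this is no check of the scan's accuracy. With 2 mice per group, SDs rest on 2 values, and the p-values measure the spread between these mice only.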

Results

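Lymph nodes were collected from 4 mice with experimental autoimmune encephalomyelitis (EAE), an induced autoimmune inflammation of the central nervous system. Of these mice, 2 had received 2-bromo-1,4-naphthalenedione (BrQ), a brominated naphthoquinone, and 2 had received vehicle. Total RNA was sequenced as 1 library per mouse. The libraries held 6992223 and 6813832 reads in gene intervals for BrQ replicates 1 and 3, and 7315568 and 7989226 for Vehicle replicates 1 and 3. A much larger part of the reads fell in no gene interval: 88.6% and 88.8% in the BrQ libraries and 87.8% and 86.8% in the Vehicle libraries.

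For most of the genome the gene names in the count tables did not appear to sit on the reads of those genes. A panel of gene families was picked by symbol, most of them used in most cell types (proteasome, respiratory chain, splicing, translation, ubiquitin, chaperone and vesicle transport genes among them). Its 752 genes outside the 5 segments named next had a median of 1.5 reads per library, and 170 reached 100 reads. The panel also took in 16 Eif1ad copies and the interferon-induced genes Usp18 and Ddx58; without these, an alternative chosen after seeing the data, the median outside was 1.75 and 169 of 735 reached 100. Foxp3, Ifng, Il10 and Mki67 had 0 reads in all 4 libraries. The mitochondrial chromosome was not put through the segment rule, and all 13 of its protein genes reached 100 reads. By the segment rule, names and reads were taken to meet in 5 segments of GRCm38, though this was not shown for each gene. The first 3 were chromosome 4 from 3549041 to 62470896, and chromosome 6 from 3372257 to 17666972 and from 28416091 to 30509783. The others were chromosome 15 from 8109273 to 38300706 and chromosome 18 from 3266048 to 10610352. Names and reads were not shown to meet on chromosome 4 between 41.77 and 42.92 Mb, a stretch that settings 1 to 3 of the rule left out. In the segments 28 of 29 panel genes reached 100 reads, a share that the segment rule itself favoured. In the order given, the segments held 15, 2, 3, 7 and 2 panel genes. Of the other genes scored, 173 of 288, 25 of 50, 16 of 28, 46 of 83 and 17 of 26 reached 50 reads. The ribosomal protein genes Rps20 and Rpl30, the 2 inside, averaged 34068 and 19334 reads, but their counts had been seen before the last setting was chosen, and settings 1 and 4 gave 3 of 4 and 2 of 4 past 100, so they are no independent check. The segments hold 572 protein-coding genes, 2.64% of those with a known position, and gene-level statements were limited to them and to the mitochondrial genes. The segment rule was chosen after seeing the data, as the last of 5 settings, and only chromosomes 4 and 15 held segments under each of the 5.

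**Figure D1:**
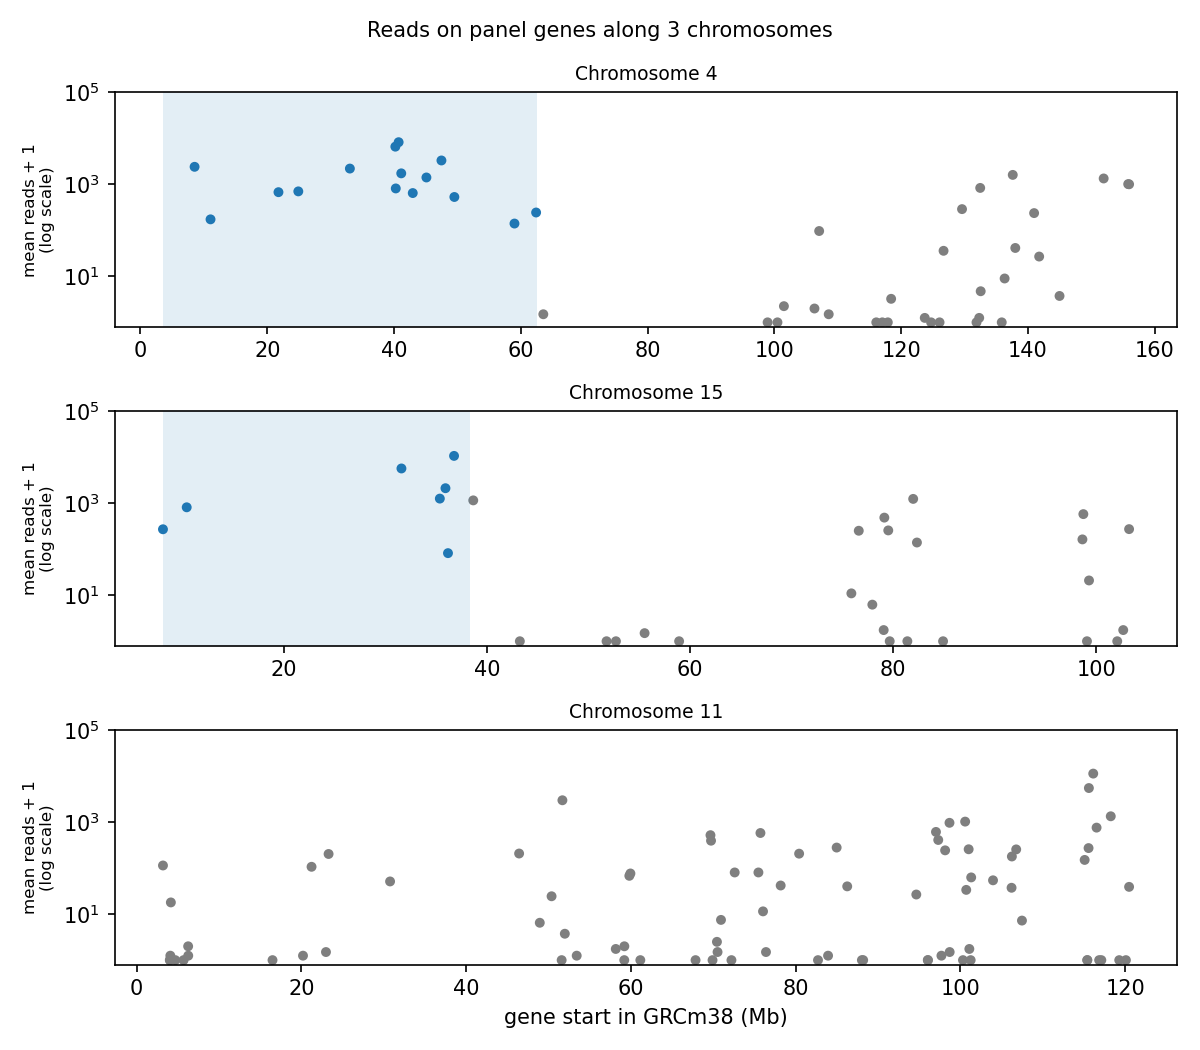
Mean reads per library plus 1 (log axis) on the panel genes, by gene start in GRCm38 (Mb), on chromosomes 4, 15 and 11. Shading marks the segments and blue points the genes inside them; inside, 28 of 29 genes over all segments reach 100 reads, while chromosome 11 has no segment.

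The comparison of BrQ with Vehicle asked which transcripts differ in the lymph node after treatment. Inside the segments, Nr4a3, an orphan nuclear receptor induced by antigen receptor signals, was 5.18-fold higher in BrQ, at 124.0 ± 0.208 CPM against 23.9 ± 2.35 (SD, n = 2 each). Ddx58, which encodes the RNA sensor RIG-I, was 3.91-fold higher, at 1393 ± 438 against 356.2 ± 27.7 CPM; it is 1 of the 29 panel genes that scored toward the segments. Trim14, an adaptor in antiviral signalling, and Tdrd7, a Tudor domain protein, were 3.43-fold and 3.20-fold higher. Gem, a small GTPase induced in activated T cells, was 3.09-fold higher. Among genes that fell, Ccdc107 went from 274.1 ± 47.5 CPM in Vehicle to 70.4 ± 2.28 in BrQ, and Arhgef39 from 106.4 ± 27.2 to 35.0 ± 1.43.

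These genes came from the rule fixed for named genes, applied inside the segments after seeing the data, which took the 10 largest changes in each direction. The log2 fold changes by edgeR's quasi-likelihood test were 2.37 ± 0.17 (SE) for Nr4a3 (adjusted p = 3.65e-05), 1.97 ± 0.20 for Ddx58 (adjusted p = 0.000131), 1.78 ± 0.22 for Trim14 (adjusted p = 0.000286) and -1.96 ± 0.17 for Ccdc107 (adjusted p = 5.85e-05), over all features tested. The other genes that rose were Prlr, Tmem67, Met, Cdh17 and Ncald, with log2 fold changes from 1.74 (Ncald) to 2.15 (Prlr). The others that fell were Fam71f2, Spag8, Gabrr2, Anks6, Phf24, Ccl27a, Colec12 and Npr2, from -2.33 (Fam71f2) to -1.50 (Npr2), all at under 20 CPM in both groups. The calls of Prlr, Fam71f2, Spag8, Anks6, Phf24, Colec12 and Npr2 were each lost with at least 1 library left out. Of the 20 genes, 12 lay inside the segments under each of the 5 settings; Tmem67, Cdh17, Gem and Phf24 did so under 4, and Met, Fam71f2, Ccl27a and Colec12 under 2. Trim14 shares 38.0% of its exonic bases with other genes, Nans among them, and Ccdc107 shares 8.0% with Rmrp. Reads on these shared parts are uncertain where strand was not used. Ccl27a has near-identical copies nearby and lies in the stretch of chromosome 4 where names and reads were not shown to meet.

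**Figure D2:**
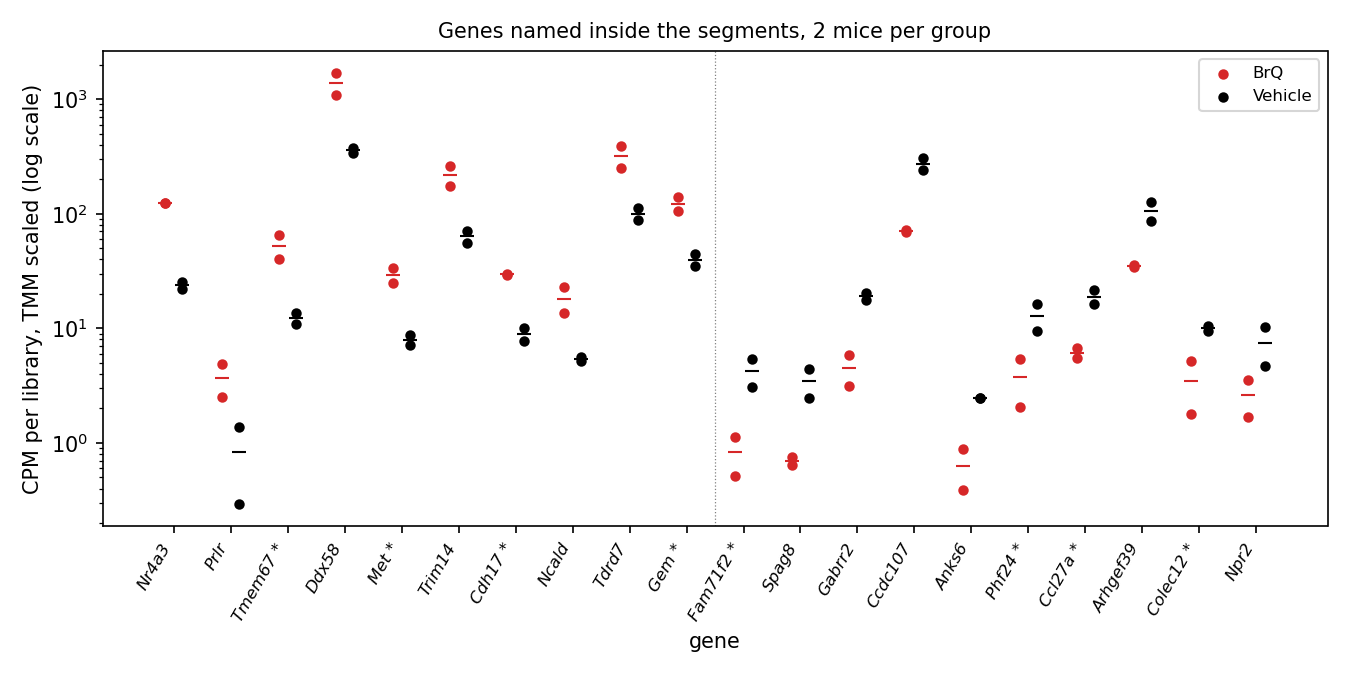
CPM per library after TMM scaling (log axis) of the 20 genes named inside the segments, rising genes left of the dotted line and falling genes right of it. Points are single mice (red BrQ, black Vehicle, 2 per group), short bars are group means, and an asterisk marks the 8 genes that were not inside the segments under each of the 5 settings. Nr4a3 stands at 124.0 CPM in BrQ against 23.9 in Vehicle.

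Of 445 features tested inside the segments, 197 passed the threshold with edgeR, 86 higher and 111 lower in BrQ. Adjusted over the features of the segments and the mitochondrial chromosome alone, 199 passed. Leaving out 1 library gave 116 (without BrQ replicate 1), 72 (without BrQ replicate 3), 193 (without Vehicle replicate 1) and 129 (without Vehicle replicate 3), and no low count filter gave 100. With a library left out its group is 1 mouse, so the spread comes from the other group alone. The split between directions moved with the segment rule: among features inside under each of the 5 settings, 104 of 230 passed, 27 higher and 77 lower. It moved with the scaling too: 146 were higher and 36 lower with library size alone, 121 and 71 with library size from all read rows, and 114 and 70 when fitted on features on their labels alone, the last 2 chosen after seeing the data. Without BrQ replicate 3, 41 were higher and 31 lower, so which direction holds more of the calls stays open. Of the 197, 195 kept their sign under every other setting that tested them. Ncbp1 and Smu1 turned from -0.36 and -0.37 to 0.01 each with library size alone. The 197 were selected as changed in these same libraries, so the kept signs are no independent support for their direction. Some further genes were picked after their values were seen. Cd72, a B cell surface protein, fell by 1.01 on the log2 scale (SE 0.12, adjusted p = 0.000285 with edgeR). Samd9l, an interferon-induced gene in a segment found only under settings 4 and 5, rose by 1.12 (SE 0.19, adjusted p = 0.00142 with edgeR), from 1274 ± 244 to 2774 ± 698 CPM.

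The mitochondrially encoded genes, which encode subunits of the respiratory chain and ATP synthase, were lower in BrQ. All 13 passed with edgeR, over all features and over the list alone, but not under each alternative. With no low count filter 7 lost the call, among them mt-Co1 (adjusted p = 0.0518, edgeR) and mt-Nd1 (adjusted p = 0.0543, edgeR). Without BrQ replicate 3, 4 lost it (mt-Atp8, mt-Co1, mt-Nd3 and mt-Nd6), and without Vehicle replicate 3, 2 (mt-Atp8 and mt-Nd3). Fitted on features on their labels alone, mt-Co1 (adjusted p = 0.573, edgeR) and mt-Cytb (adjusted p = 0.0830, edgeR) lost it; no sign changed. Mt-Cytb went from 46811 ± 15213 CPM in Vehicle to 16506 ± 4021 in BrQ, mt-Nd1 from 26923 ± 11085 to 10246 ± 2376, and mt-Co1 from 148124 ± 51728 to 67604 ± 9856 (SD, n = 2 each). Mitochondrial reads made up 15.8% and 12.1% of gene reads in the BrQ libraries and 20.6% and 30.3% in the Vehicle libraries. Of all 23 mitochondrial features tested, 22 were called lower, 11 without BrQ replicate 3, 15 without Vehicle replicate 3, 17 with DESeq2 and 8 of 24 with no low count filter. The list was the only 1 of 35 tested to pass with camera at a preset correlation of 0.01 (adjusted p = 2.03e-05, limma). It did not pass with an estimated correlation (adjusted p = 0.833, limma camera) or with fry (adjusted p = 0.160, limma). No other list had more than 1 tested member inside the segments, so passing alone does not show that the change is particular to these genes. Parts of mt-Co1, mt-Co2, mt-Atp8, mt-Atp6 and mt-Co3 have near-identical nuclear copies, so their reads are uncertain.

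Other members of the fixed lists inside the segments were few, and 3 had too few reads to be tested. Ccl19 and Ccl21a, chemokines of lymph node stroma, held 27, 8, 5 and 0 reads and 0 in all 4 libraries, in the order BrQ 1, BrQ 3, Vehicle 1 and Vehicle 3. They lie in the stretch of chromosome 4 that settings 1 to 3 left out. Lep, of the adipocyte list, also held 0 reads. Il7r, the interleukin 7 receptor of naive T cells, fell by 0.61 on the log2 scale (SE 0.14, adjusted p = 0.00616 with edgeR), from 856.4 ± 62.6 to 562.2 ± 63.3 CPM, and lost the call with library size alone (-0.23, adjusted p = 0.278 with edgeR) and without BrQ replicate 1. Pax5, the B cell transcription factor, stood at 1067 ± 46.7 CPM in BrQ and 1246 ± 12.7 in Vehicle and did not pass (adjusted p = 0.155 with edgeR). Basp1, of the germinal centre list, did not pass either, at 75.4 ± 1.48 against 81.7 ± 7.06 CPM. Col1a2, a fibroblast collagen, fell by 0.78 (SE 0.26, adjusted p = 0.0352 with edgeR) and lost the call under 8 alternatives, library size alone and no low count filter among them. It lies in a segment found only under settings 4 and 5, as does Asns. Asns, of the stress response list, did not pass, at 27.8 ± 1.03 against 33.9 ± 10.2 CPM. Nr4a3 belongs to the immediate early list.

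The series title asks about CD8 T cells and Th1 and Th17 differentiation, and no member of those 3 lists lay inside the segments. The values under their names are given as fixed beforehand and were not shown to be readings of those genes. Of the CD8 T cell and cytotoxic list, 5 of 20 intervals were tested, 0 were higher and 1 was lower (camera adjusted p = 0.995, limma); of the Th1 list, 5 of 8 were higher and 1 lower (adjusted p = 0.264, limma camera); of the Th17 list, 0 of 5 were higher and 2 lower (adjusted p = 0.551, limma camera). Adjusted over the list alone, the numbers passing were 1, 7 and 2. The interval labelled Cd8a did not pass (log2 fold change 1.23, adjusted p = 0.111 with edgeR) but passed as higher with library size alone (1.59, adjusted p = 0.0300 with edgeR). That labelled Cd4 passed as lower (log2 fold change -1.49, adjusted p = 9.11e-05 with edgeR). The interval labelled Cd8a held 46, 20, 17 and 7 reads and that labelled Cd4 777, 762, 1870 and 1837, in the order BrQ 1, BrQ 3, Vehicle 1 and Vehicle 3. The log2 ratio of the first to the second was -4.66 ± 0.83 in BrQ and -7.41 ± 0.89 in Vehicle (SD, n = 2 each), a difference of 2.74 with p = 0.33 in a two-sided exact permutation test, the smallest p that 2 against 2 allows. The interval labelled Cd8b1 held 11, 2, 0 and 0 reads, Tbx21 10, 7, 10 and 3, Il17a 55, 44, 54 and 57, and Gzmb 0, 5, 0 and 0.

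Over all intervals, whatever RNA their names stand for, 4676 of 10223 tested passed with edgeR, 2409 higher and 2267 lower in BrQ. With library size alone the split was 3607 higher and 1072 lower, and with library size from all read rows, chosen after seeing the data, 3060 and 1587. Without BrQ replicate 3 the count was 2031, and with no low count filter 2481. The 10 largest rises lay on intervals labelled Psca, Fam162a, U90926, Usp17lb, Ifit1bl1, Slfn2, Copb1, Nptx1, Rnf144a and Opn5, and the largest falls included those on Ice2, Vps26c, Rtp1, Rpl19, Ube2d2b, Shisa7, mt-Atp8, B4galt5 and Scube3. With no low count filter Fam162a, Opn5, Ice2, B4galt5 and mt-Atp8 lost the call, as did B4galt5 without BrQ replicate 3 (adjusted p = 0.0816, edgeR). The fall of mt-Atp8 rests on Vehicle replicate 3: it held 37 and 14 reads in BrQ and 54 and 493 in Vehicle, and without that library its log2 fold change went from -3.67 to -1.28 and no longer passed. The interval labelled Slfn2 held 3343 and 7273 reads in BrQ and 103 and 79 in Vehicle. Of the type I interferon list, 5 of 7 tested intervals were higher and 1 lower (camera adjusted p = 0.0773, limma), none of them inside the segments.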

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

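The tests of both patterns here were chosen after the results were seen. Reads in no gene interval were flagged: their share averaged 88.7% in BrQ and 87.3% in Vehicle, with both BrQ libraries above both Vehicle libraries. Mitochondrial reads took 1.78% and 1.33% of all read rows in BrQ replicates 1 and 3. In Vehicle replicates 1 and 3 they took 2.48% and 3.92%. Fewer mitochondrial reads leave a larger share in no gene interval, so this gap was not shown to be separate from the mitochondrial fall.

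Genes of families used in most cell types mostly had few or no reads outside the segments, while the same libraries filled the mitochondrial chromosome. Counting on the wrong strand is argued against, because mt-Cytb held 7.65 times the reads of mt-Nd6, which lies on the opposite strand, where that error would give mt-Nd6 the excess. A candidate explanation is gene models of another assembly laid over reads aligned to mm10. In a scan of 196 windows, 35 had a best shift past all 50 permutations. Of these, 14 shared the shift of their chromosome, against at most 4 in 1000 draws of uniform shifts. The draws spread shifts evenly up to 1000 kb either way and took windows as independent, so 4 is not a full measure of chance agreement. The 14 windows lay on 5 chromosomes, with 5 of 5 passing windows of chromosome 11 within 10 kb of a shift of -109.6 kb. The other 21 shared their shift with no other passing window, and 13 chromosomes had 1 window at their commonest shift. Windows that missed their permutations were left out of these counts. Some gave nearly the shift of a passing neighbour, as on chromosomes 8 (730.3 kb beside 729.45 kb) and 17 (218.05 kb beside 220.2 kb). Others did not, as on chromosome 19 (-23.3 kb beside 49.65 kb), and how many agreed was not counted. In a simulation without a shift 0 of 12 windows passed their permutations. The score is centred, which sets it at or near 0 for a shift of 0 (at most 0.605 SD in absolute value), so the scan cannot show where names and reads meet. None of the 4 windows centred in the segments passed, and 3 outside passed with a best shift within 1 kb of 0. Neither outcome shows whether names there are in place. A window holds at least 40 genes, so displacement was not shown for each gene. The annotation used was not analysed here, so this stays a hypothesis, and no biological explanation was tested.

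Mitochondrial transcripts were lower in BrQ. Scaling to the reads in gene intervals is argued against as the whole cause, since the median log2 fold change of the 13 genes was -1.28 with library size from all read rows, against -1.50 in the main comparison. Vehicle replicate 3 had the highest mitochondrial share. Without it the median was -1.01, but Vehicle is then 1 mouse, so whether replicate 3 is the only source cannot be decided. The calls left without it rest on the spread of BrQ and are not used here. The mean log2 CPM of these genes was 9.69 and 9.10 in BrQ replicates 1 and 3. In Vehicle replicates 1 and 3 it was 10.55 and 11.61, so Vehicle replicate 1 also stood above both BrQ libraries. The SD between mice of this mean was 0.42 in BrQ and 0.75 in Vehicle. An effect of treatment, and a difference between 2 and 2 mice in tissue handling or cell makeup, stay open and were not tested.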

How the results depend on the processing

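The count over all intervals (4676) stayed within 1.5 times under the alternatives fixed beforehand except no low count filter (2481) and leaving out a library (2031 to 4376); with features on their labels alone, which tests fewer features, it was 204. Inside the segments the count (197) fell to 100 with no low count filter, ranged from 72 to 193 with a library left out, and was 195 without the chromosome 4 stretch and 104 for features inside under each of the 5 segment settings. Under settings 1 to 4 it was 160, 151, 151 and 294, with 23.8%, 39.7%, 39.7% and 44.9% of them higher, against 43.7% as reported, so the direction split there depends on the segment rule, and on the scaling too. The alternatives for segments, features on their labels, mitochondrial features, all read rows, crossed numbers and the panel, and the genes described beside the rule, were chosen after seeing the data. Gene lists called numbered 1, then 0 with an estimated correlation (mitochondrial list adjusted p = 0.833, limma camera), with fry and without mitochondrial features, 2 with the replicate block, and 2 to 3 with a library left out, where the type I interferon list passed each time. The CD8 list, never past the threshold, turned to lower with library size alone (adjusted p = 0.943), all read rows (0.975), crossed numbers (0.973) and 3 of the 4 libraries left out in turn (range over the 4 0.813 to 0.994, limma camera). Library size alone moved the median of all features from 0.05 to 0.42, and all read rows to 0.25. The Cd8a to Cd4 difference kept its sign with each library left out; Cd8b1 in its place gave no value, because Vehicle held 0 reads. No gene of the rule reversed; Cd8a gained the call with library size alone (1.59). Inside the segments, Anks6, Colec12, Fam71f2, Npr2, Phf24, Prlr and Spag8, all with few reads, lost the call under at least 1 alternative fixed beforehand, and so did Fam162a, Opn5, Ice2 and B4galt5 among the intervals. Of the 13 mitochondrial genes 7 lost it with no low count filter, 4 without BrQ replicate 3 and 2 without Vehicle replicate 3, the abundant mt-Co1 and mt-Nd1 among them. Of the genes described beside the rule, Col1a2, Il7r, Irf5, Melk, Sit1, Smc2 and Tox lost it. Others, not called, changed sign: with library size alone Asns (0.10), Bach2 (0.36), Basp1 (0.26), Pax5 (0.15) and Rpl30 (0.12); with all read rows Bach2 (0.20) and Basp1 (0.10); on their labels alone Bach2 (0.16) and Basp1 (0.0507); Bach2 with no low count filter (0.0288) and with a CPM of at least 1 (0.00256); and with a library left out Asns (-0.59 to 0.0441) and Bach2 (-0.11 to 0.0760). Replicate numbers come from different mice and do not pair them (correlation of deviations -0.12 over 2 pairs); the replicate block gave 4190 calls over all intervals and 167 inside the segments, and the crossed pairing 5284 and 225.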

Other observations

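Further genes inside the segments are given as values, picked after their values were seen, with edgeR's quasi-likelihood adjusted p over all features. Lyn, a Src family kinase of B and myeloid cells, was 1.75-fold higher in BrQ, at 1143 ± 94.8 CPM against 652.4 ± 53.5 (SD, n = 2 each; adjusted p = 0.00125, edgeR). Txn1, the cytosolic thioredoxin, was 1.71-fold higher (adjusted p = 0.00117, edgeR), and Tox, a T cell transcription factor, was 1.65-fold higher (adjusted p = 0.00682, edgeR). The mitotic kinase gene Melk and the condensin gene Smc2 were 1.53-fold and 1.49-fold higher; Tox, Melk and Smc2 lost the call with at least 1 library left out. Crem, a cAMP-responsive transcription factor, was 2.40-fold higher but lay in a segment found only under settings 4 and 5, as did Irf5, an interferon regulatory factor, at 1.31-fold, a call lost with each single library left out and with DESeq2. Sit1, a lymphocyte signalling adaptor, fell by 0.78 on the log2 scale (SE 0.16), a call lost with library size alone and without BrQ replicate 3. Rps20, outside the segments under setting 1, fell by 0.82 (SE 0.12), while Rpl30 did not pass (adjusted p = 0.125, edgeR). Bach2, a lymphocyte transcription repressor, stood at 218.4 ± 13.6 and 219.0 ± 21.5 CPM.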
